A study of Mus musculus with 2 samples.

How the data were processed

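The series holds chromatin immunoprecipitation with sequencing (ChIP-seq) for histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, from mouse forebrain at postnatal day 0. The 2 samples form 1 group and are biological replicates 1 and 2 per the labels. Each is a pool of tissue from male and female mice of a mixed B6NTac and B6NCrl background. Replicate 1 came from 15 mice, and the number behind replicate 2 is not given in the sources used here. There is no second condition, so the comparisons are between the replicates and between parts of the genome.

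The authors deposited 4 peak lists on the mm10 build: a list for each replicate, a list called on both replicates together (pooled), and a list of replicated peaks. Per the accompanying text files, each replicate was called against the same 2 control files, so any artefact of the controls is shared by both lists and can count as agreement. The aligner, the peak caller and their versions are not given in the sources used here. Each peak has a signal value, the enrichment over control as the authors deposited it, with 1 value per peak. Each peak also has deposited −log10 p and −log10 q values. The smallest −log10 p was 2.00 in replicate 1 and 2.32 in the replicated list, so the lists include weak peaks, and 9.68% of replicate 1's peaks and 11.5% of replicate 2's had q above 0.05. All rows of the replicated list on the main chromosomes are rows of the pooled list, checked on the files. The files hold no read counts, so the depth of each library is unknown, and a site without a peak was below the caller's threshold at that depth.

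Positions were compared with the GRCm38.p6 sequence, the same build as mm10, and 0 peaks passed a chromosome end. Genes came from GENCODE M21: 21851 protein-coding genes with 41438 transcription start site (TSS) positions on the main chromosomes. A promoter peak lay within 1 kb of a TSS, and a distal peak overlapped no such window. Other peaks were classed by their midpoint as exon, intron or intergenic. All values of a gene's promoter are the highest signal value among its promoter peaks, and the mean and SD are over the 2 replicates' own lists. Signal values were not rescaled between the lists.

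Peaks were called shared when they overlapped by at least 1 bp, and chance overlap came from 100 shifts of the peaks along their chromosomes. Intervals of shares are exact binomial at the 95% level and cover counting error only. The 21 gene lists, with 307 genes in all, were fixed before the data were examined, and 0 members were unmatched. Promoter peaks per list were compared with all other protein-coding genes by two-sided Fisher's exact test. Distal peaks within 50 kb of any TSS of a gene were compared with 10000 random lists, by a two-sided permutation test whose smallest p is 0.0002. The random lists were matched in quintiles on the number of coding genes within 100 kb, by each gene's median TSS position. They were not matched on the number or spread of a gene's own TSSs, which sets the length searched. Both were adjusted by Benjamini-Hochberg over the 21 lists, at a threshold of 0.05. Distal peaks less than 12.5 kb apart were joined, and the clusters were ranked by the sum of signal value times width. The strongest were those past the point where the scaled ranked curve reaches slope 1. The 19 consensus motifs were searched on both strands in 500 bp windows on distal peaks and in as many windows shifted by 5 to 20 kb, free of peaks and matched on GC content within 1 percentage point, by Fisher's exact test with Benjamini-Hochberg adjustment. Replicate differences per list were placed among 10000 random lists matched on signal, with no p-value, since each side has 1 library. Genes and peaks are not independent replicates, so the tests describe these 2 pools and not the spread between animals.

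Named genes followed a rule fixed before the data were examined. Per list it takes up to 4 members with a promoter peak and the highest mean signal. It also takes the members without a peak where these are 4 or fewer or, in lists where under 50% of members have a peak, up to 4 members with one. It further takes the 10 genes with the widest replicated promoter peak, the 10 with the highest mean signal, the 15 highest distal clusters, the 5 largest replicate differences each way among genes above the median signal, and the 10 genes with most distal peaks. The gene nearest to a cluster is given as a position and not as a target.

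The functions were tested on simulated data. For the replicate overlap, 19931 peaks simulated with 60.0% shared gave 60.3%. For the promoter lists, over 21851 genes, 3 of 3 lists set high and 3 of 3 lists set to none were called, with 0 of 15 others. For the distal lists, over the same genes, 3 of 3 lists with added peaks were called, as was 1 of 18 others. That other list was Hox (ratio 1.87, adjusted p = 0.00105 by permutation), whose members lie side by side and do not count as independent genes. For the motifs, a motif written into 5.18% of 4000 windows was called, with a difference of 4.83 percentage points, and 0 others were called. For the replicate differences, over 11391 genes, a list raised 1.5-fold left its random range and 0 of 10 others did.

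The alternatives were a stricter threshold (−log10 q of at least 5), other overlap rules, promoter distances, windows and joining distances, each replicate's own list in place of the replicated list, backgrounds matched on promoter CpG ratio, and motif windows not matched on GC. Further alternatives were added after the data were seen: 1 member per 100 kb, the pooled list, distal peaks defined against all annotated TSSs, promoter values matched through the replicated peak, the strongest quintile of distal peaks, and motif windows with under 10% soft-masked repeats. Peaks on sequences outside the chromosomes were left out of every comparison. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.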

Results

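H3K27ac was mapped in 2 pools of newborn mouse forebrain, and peaks were called in each. Replicate 1 had 74853 peaks covering 35.3 Mb (1.29% of the genome), with a median width of 272 bp and a median signal value of 3.90. Replicate 2 had 82732 peaks covering 39.3 Mb (1.44%), with a median width of 278 bp and a median signal value of 3.77. The pooled list held 98617 peaks, of which 47425 were in the replicated list. The replicated peaks covered 38.7 Mb, with a median width of 553 bp and signal values up to 71.7. Read depth was unknown, since the files give no counts.

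The first comparison asked how far the replicates shared their acetylated sites. Of the replicate 1 peaks on the chromosomes, 47896 of 74842 (64.0%, exact 95% interval 63.7 to 64.3) overlapped a replicate 2 peak. In the other direction 46597 of 82721 (56.3%, 56.0 to 56.7) did so. After shifting the peaks along the chromosomes these shares averaged 2.79% and 2.497%. Sharing depended on strength: in the highest signal quintile 99.6% of replicate 1's and 98.9% of replicate 2's peaks were shared, and in the lowest quintile 38.3% and 28.7%. Promoter peaks were shared more often (88.4% and 83.0%) than intronic peaks (54.7% and 47.7%). Over 41353 matched peak pairs the signal values had a Spearman correlation of 0.765 across peaks, which are not independent replicates, and 98.6% of pairs lay within 2-fold. Signal values spanned a narrow range, with quartiles of 3.19 and 5.15 over all replicate 1 peaks and 3.18 and 5.09 over all replicate 2 peaks. Many pairs may thus lie within 2-fold by chance, and no chance level was computed. Because both replicates were called against the same control files, part of this sharing may rest on the controls.

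**Figure D1:**
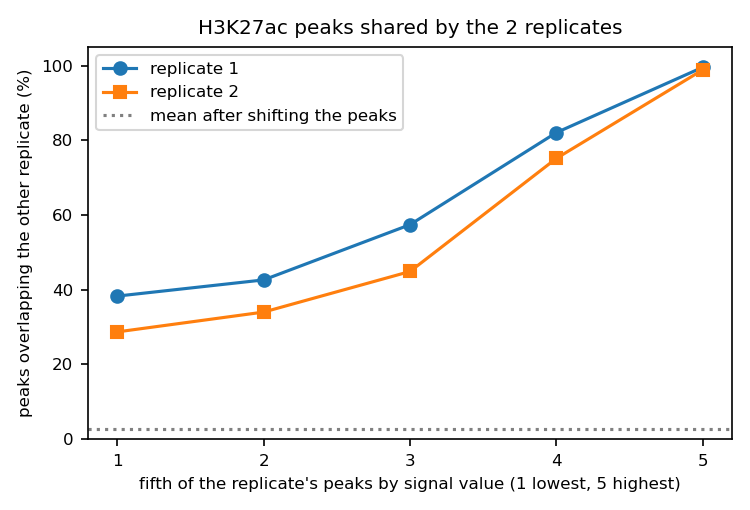
Share of each replicate's peaks that overlap the other replicate (y axis, %) by quintile of the replicate's own signal value (x axis, 1 lowest). Sharing goes from 38.3% and 28.7% in the lowest quintile to 99.6% and 98.9% in the highest, against means of 2.79% and 2.497% for all peaks after shifting.

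In the replicated list, 68.4% of peaks had at least 50% of their length covered by peaks of each replicate, and 84.2% were touched by peaks of both. Of the 51186 pooled peaks outside the replicated list, 1.05% were touched by peaks of both replicates. The replicated list therefore also holds peaks that at least 1 replicate's own list lacks, and its exact criterion is not given in the sources used here.

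The mark was concentrated at promoters. Of the replicated peaks, 14165 (29.9%) lay within 1 kb of a coding TSS, against a mean of 2.92% after shifting (two-sided permutation p = 0.0198, the smallest that 100 shifts can give). Promoter peaks were wider (median 908 bp) and stronger (median signal 8.79) than intergenic peaks (480 bp, 4.28), and they held 42.0% of the covered length. Introns held 41.1% of peaks, close to the 40.8% after shifting (range 38.6% to 42.4%, permutation p = 0.634). This depended on the list, since introns held 46.1% and 46.9% in the replicates' own lists, 49.7% in the pooled list and 35.2% of replicated peaks at the stricter threshold. Intergenic sequence held 23.4%, against 52.0% after shifting (permutation p = 0.0198). The promoter share was lower in the replicates' own lists, at 23.6% and 21.9%, and 18.5% in the pooled list.

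A replicated promoter peak was present at 11567 of the 21851 protein-coding genes (52.9%). The widest lay at Meis2, a homeobox transcription factor gene, and ran for 21659 bp on chromosome 2 from 116055051 to 116076709 (mm10). Next were Nfix (18408 bp), a nuclear factor I gene, Tnrc18 (14677 bp), and Foxg1 (13863 bp, chromosome 12 from 49373270 to 49387132), a regulator of telencephalon development whose peak also covers a TSS of Gm43517. Pou3f3 (12732 bp), Mn1 (12567 bp), Bcl11a together with A830031A19Rik (12104 bp, a single peak over both) and Islr2 (11868 bp) followed. The highest mean signal values were at Klf7 (60.4 ± 1.85, SD, n = 2), Nrf1 (54.9 ± 2.82), Sp3 (52.5 ± 1.10), Ywhaz (51.8 ± 6.02), Kmt2e (51.7 ± 6.80), Tnrc18 (51.7 ± 2.21), Epc1 (51.5 ± 0.161), Gabpb1 (50.9 ± 2.66), Wac (50.5 ± 3.89) and Pogz (50.1 ± 0.0519). Several of these encode general transcriptional or chromatin regulators. Width and signal therefore named different genes, with only Tnrc18 in both groups of 10.

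The gene lists asked which cell types and regions left their mark at promoters. All 16 pan-neuronal genes carried a promoter peak (adjusted p = 0.000229, Fisher's exact test), led by the adhesion molecule gene Ncam1 (26.8 ± 0.864, SD, n = 2), the neuronal tubulin gene Tubb3 (25.4 ± 2.22), Mapt (24.2 ± 2.41) and Map2 (22.5 ± 2.04). All 12 forebrain patterning factors did so (adjusted p = 0.00180, Fisher's exact test), with Foxg1 at 35.3 ± 3.79, Nr2f1 at 28.8 ± 0.207, Lhx2 at 13.5 ± 0.938 and Nr2f2 at 13.1 ± 0.528. Of the glutamatergic lineage genes 17 of 19 carried a peak (adjusted p = 0.00234, Fisher's exact test). The highest were Foxp1 (26.0 ± 0.131), Satb2 (20.8 ± 0.714), Bcl11b (19.8 ± 3.38) and Neurod6 (19.7 ± 1.47), all of them transcription factor genes. The pools hold mixed forebrain cells, so these peaks cannot be assigned to a single lineage. The 2 without a replicated peak were Neurog1 and Eomes, and Eomes had a peak in replicate 1's own list. Of the radial glia and astrocyte genes 17 of 19 carried a peak (adjusted p = 0.00234, Fisher's exact test), with Nfib at 34.8 ± 2.97, Glul at 20.7 ± 5.27, Sox2 at 13.6 ± 2.12 and Nfia at 11.1 ± 0.370, while Nes and S100b had no replicated peak. Nes had a weak peak in both replicates' own lists (3.19 and 3.60). The Glul peak also lay within 1 kb of a TSS of Teddm2. Of the other radial glia and astrocyte genes with a replicated peak, only Slc1a2 (10.6) passed 10.3, the median over genes with a promoter peak in both replicates. Lower values included Aldoc at 5.15, Gja1 at 5.05, Gfap at 4.68, Apoe at 4.49, Slc1a3 at 4.25 and Aldh1l1 at 3.76. All 20 housekeeping genes carried a peak (adjusted p = 3.41e-05, Fisher's exact test), led by Ywhaz, Actb (40.1 ± 2.57), Eef1a1 (29.9 ± 3.71) and Ppia (29.3 ± 2.39). Against genes of like promoter CpG ratio all 5 lists stayed higher with smaller differences, at 100% against 80.2% for housekeeping (adjusted p = 0.0234), 70.4% for forebrain factors (0.0336) and 59.5% for pan-neuronal genes (0.00140), and at 89.5% against 66.2% for glutamatergic (0.0336) and 57.6% for radial glia and astrocyte genes (0.00210, all permutation tests). The radial glia and astrocyte call was lost at the stricter peak threshold (adjusted p = 0.0891, Fisher's exact test).

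**Figure D2:**
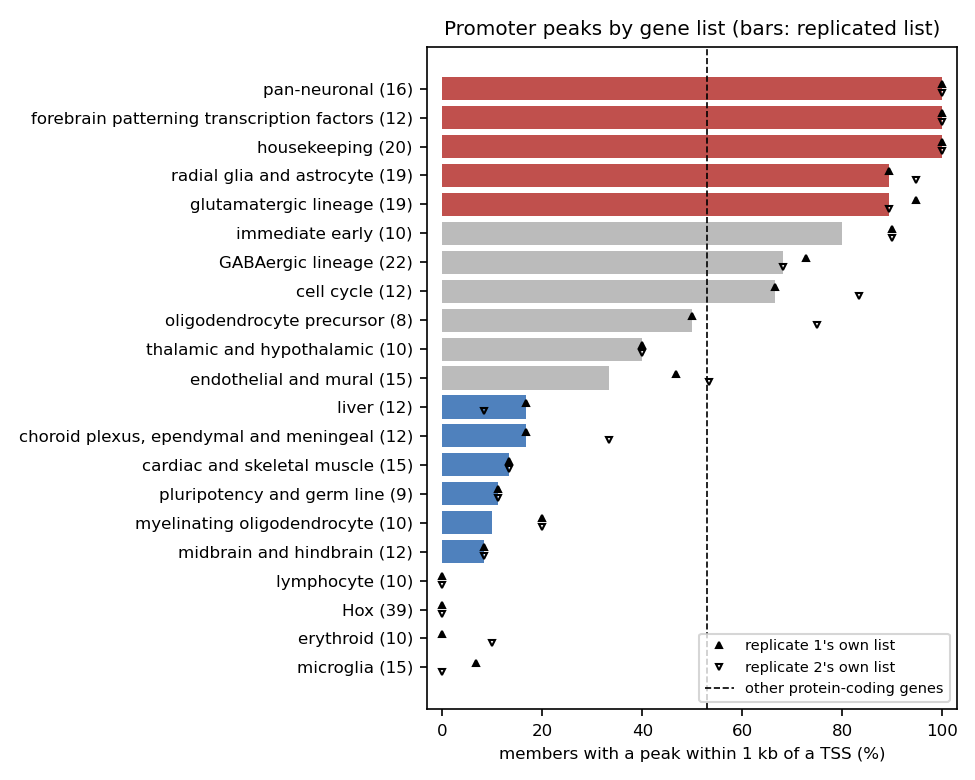
Share of each list's members (number in brackets) with a peak within 1 kb of a TSS (x axis, %), as bars for the replicated list and triangles for the replicates' own lists. Red bars are above and blue bars below the other protein-coding genes (dashed line, 52.9%) at an adjusted p under 0.05, and grey bars are not called. Hox, microglia, erythroid and lymphocyte bars are at 0.

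Other lists were not told apart from the remaining genes. Of the GABAergic lineage genes 15 of 22 carried a peak (adjusted p = 0.233, Fisher's exact test). Meis2 (19.3 ± 2.40, SD, n = 2), Dlx6 (18.9 ± 0.280) and the GABA synthesis genes Gad1 (17.7 ± 1.95) and Gad2 (17.5 ± 1.39) were highest. The 7 without a replicated peak, named here after their values were seen, were Gsx1, Gsx2, Lhx8, Sst, Npy, Pvalb and Calb2, of which Lhx8 had a peak in replicate 1's own list and Npy in that of replicate 2. Of the immediate early genes 8 of 10 carried a peak (adjusted p = 0.151, Fisher's exact test), with Dusp1 at 22.7 ± 0.0777, Jun at 17.9 ± 0.136, Egr1 at 11.7 ± 2.00 and Ier2 at 6.73 ± 0.0739, and Fosb and Nr4a1 without a replicated peak, although Nr4a1 had a weak peak in both replicates' own lists (3.55 and 2.90). This list was called higher at 2.5 kb (adjusted p = 0.0422) and in replicate 1's own list (0.0350, both Fisher's exact test). Of the cell cycle genes 8 of 12 did so (adjusted p = 0.439, Fisher's exact test). Birc5 had 28.3 ± 0.147, Ccna2 16.0 ± 1.02, Mcm5 13.7 ± 1.37 and Mcm2 7.89 ± 3.46, while Mki67, Ccnb1, Cdk1 and Bub1 had no replicated peak, the first 3 of them having a peak in the own list of a single replicate. In the pooled list the cell cycle genes were called higher (adjusted p = 0.00354, Fisher's exact test). Oligodendrocyte precursor genes had 4 of 8, namely Olig2 (5.44 ± 0.173), Sox8 (4.99 ± 0.870), Olig1 (4.87 ± 0.138) and Nkx2-2 (3.34 ± 0.576), and lacked a replicated peak at Sox10, Pdgfra, Cspg4 and Gpr17, of which Pdgfra and Cspg4 had a peak in replicate 2's own list. Thalamic and hypothalamic genes had 4 of 10 (Prox1 6.90 ± 0.829, Tcf7l2 6.02 ± 0.636, Lhx9 3.93 ± 0.547, and Lef1, listed in replicate 1 alone at 4.26). Endothelial and mural genes had 5 of 15, among them Slc2a1 (6.13 ± 1.02), Pdgfrb (5.05 ± 0.389), Cldn5 (4.14 ± 0.333) and Slco1c1 (3.96 ± 0.584).

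Of the lists of other tissues, other brain regions and minor cell types, 10 had fewer replicated promoter peaks than the remaining genes. No replicated promoter peak was found at any of 39 Hox genes (adjusted p = 3.47e-12), 15 microglial genes (8.57e-05), 10 erythroid genes (0.00180) or 10 lymphocyte genes (0.00180, all Fisher's exact test). Of the midbrain and hindbrain genes 1 of 12 had a peak, Egr2 (4.91 ± 0.281, SD, n = 2), which is also an activity-induced gene (adjusted p = 0.00460, Fisher's exact test). The myelin list had 1 of 10, Cnp (4.34 ± 0.614, adjusted p = 0.0144, Fisher's exact test). The choroid plexus, ependymal and meningeal list had 2 of 12, Foxj1 (6.35 ± 0.549) and Foxc1 (4.67 ± 0.420), and the liver list 2 of 12, Trf (4.54 ± 0.327) whose peak also lay within 1 kb of a TSS of Gm20425, and Fga (replicate 1 alone, 3.403), both with adjusted p = 0.0241 by Fisher's exact test. The muscle list had 2 of 15, Myh7 (20.7 ± 3.78) and Nppa (3.14 ± 0.617, adjusted p = 0.00549, Fisher's exact test), and the pluripotency and germ line list 1 of 9, Dazl (7.08 ± 1.02, adjusted p = 0.0241, Fisher's exact test). Against genes of like promoter CpG ratio, the microglial (0% against 19.3%, adjusted p = 0.0599) and choroid plexus lists (16.7% against 40.8%, 0.0805) stayed below the 95% range of matched lists but did not pass after adjustment, and the muscle list (13.3% against 22.6%, 0.714) lay within its range in the permutation test, while Hox and midbrain and hindbrain (both 0.00140), pluripotency (0.0218) and myelin genes (0.0336) stayed lower and the thalamic and hypothalamic list (40.0% against 80.2%, 0.0234) became lower. For the erythroid, lymphocyte and liver lists, matched genes had a peak in only 9.41%, 15.4% and 18.7% of cases and the 95% range of matched lists began at 0, so that test could not call these lists lower and says nothing on them. The microglial list, at 0%, already had the lowest share possible. The test could therefore not call it lower after adjustment, and its loss does not show that CpG content accounts for the deficit. The myelin (adjusted p = 0.256), liver (0.223) and choroid plexus (0.0701) calls were also lost at 2.5 kb by Fisher's exact test, as were the liver call with 1 member per 100 kb (0.0755), the myelin call in replicate 1's own list (0.0684) and the pooled list (0.137), and the choroid plexus call in replicate 2's own list (0.186) and the pooled list (0.165). The Hox genes lie in tight clusters, and with 1 member kept per 100 kb 0 of 6 had a peak (adjusted p = 0.0190, Fisher's exact test).

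Of the replicated peaks 33253 (70.1%) were distal. The distal peaks within 50 kb of any TSS of a gene were most numerous around the neuronal transcription factor gene Tcf4 (89), Celf2 (47), Foxp1 (39), Trak1 (35), Abr (34), Fyn (33), Msra (33), Gramd1b (32), Gse1 (32) and G430095P16Rik (30), while the median gene had 0. G430095P16Rik lies within Nfix (28 distal peaks), so the counts of these genes can hold the same peaks. Every TSS of a gene was used, so genes with widely spread TSSs were searched over more sequence. The ranking was not adjusted for that length, and the random lists below were not matched on it. Glutamatergic lineage genes had 10.1 distal peaks on average, with a median of 5, against a mean of 1.76 in matched random lists (5.75-fold, adjusted p = 0.00210, permutation test). Forebrain patterning factors had 9.75 (5.18-fold, adjusted p = 0.0112, permutation test). GABAergic lineage genes had 4.68 (2.78-fold, adjusted p = 0.0199, permutation test), although their promoters did not stand apart. Radial glia and astrocyte genes had 5.05 (2.91-fold) and immediate early genes 4.90 (3.13-fold), both with adjusted p = 0.0300 by permutation. Pan-neuronal genes had 4.25, which did not pass (2.34-fold, adjusted p = 0.0803, permutation test), and neither did oligodendrocyte precursor genes (4.88, adjusted p = 0.0709, permutation test). Pan-neuronal genes did pass with the own list of replicate 1 (adjusted p = 0.0304) or replicate 2 (0.0434), and oligodendrocyte precursor genes with that of replicate 2 (0.0304), and muscle genes were called higher with a 200 kb window (0.00140, all permutation tests). Midbrain and hindbrain genes had 0.167 (0.0948-fold, adjusted p = 0.0300, permutation test) and Hox genes 0 (adjusted p = 0.00210, permutation test). The same test also called the Hox list in simulated data with no effect set for it (ratio 1.87). Its members lie side by side, so its p-value cannot be taken as evidence of a deficit. With 1 member per 100 kb the Hox list still had 0 distal peaks against 1.53, but with 6 members it was not called (adjusted p = 0.0709, permutation test). A mean of 0 is the lowest possible, so with 6 members the test could not call the list lower. It therefore does not decide whether clustering made the deficit. With a 200 kb window the forebrain factor (0.134), GABAergic (0.102) and midbrain and hindbrain (0.561) calls were lost. The midbrain and hindbrain call was also lost at 20 kb (0.0819) and at the stricter threshold (0.148, permutation tests).

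**Figure D3:**
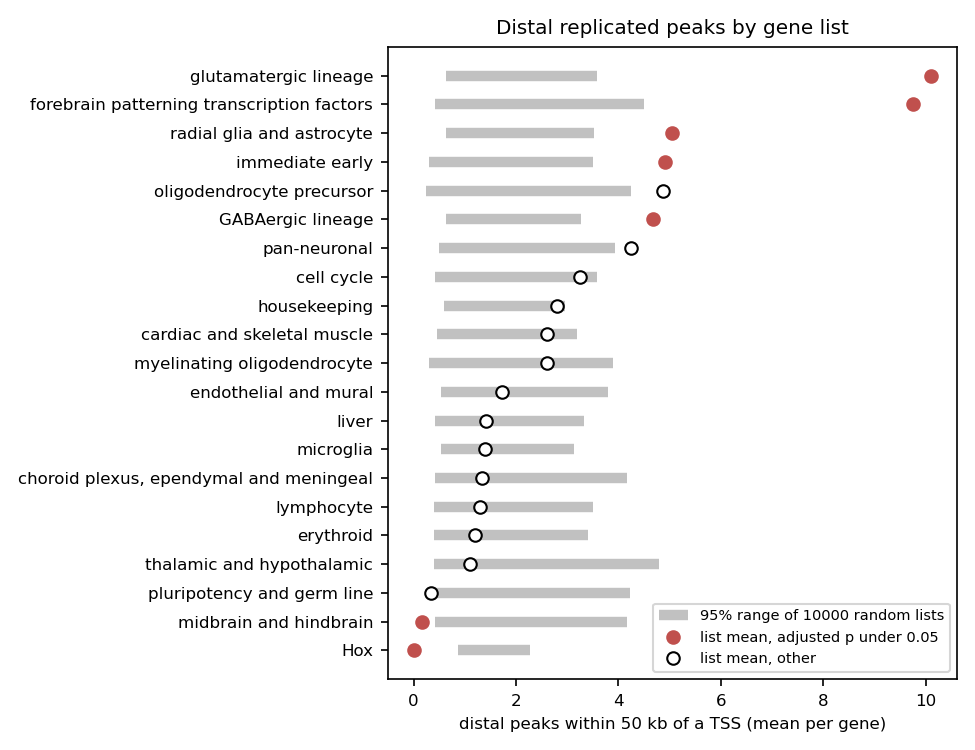
Mean number of distal replicated peaks within 50 kb of a TSS (x axis) per gene list (points), with the 95% range of 10000 random lists matched on gene density (grey bars). Glutamatergic genes (10.1) and forebrain patterning factors (9.75) lie farthest above their ranges, and Hox genes lie at 0.

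Joining distal peaks gave 16005 clusters, of which 472 lay past the slope point and held 34.7% of the summed signal times width. The highest 3 lay at chromosome 7, 79496144 to 79550190 (nearest coding gene Polg), chromosome 13, 83706687 to 83751209 (Mef2c, at a distance of 131010 bp), and chromosome 3, 88197588 to 88242584 (Rhbg). The others among the first 15 were nearest to Cstad, Wnt7b, Kif13b, Ubash3b, Chd2, Tuba1a, Celf2, Tcf4, Add2, Prss52, Sdccag8 and Lrrc74a. Among list members nearest to a cluster past the slope point were 6 of 19 glutamatergic genes (Bcl11b, Foxp1, Mef2c, Neurod2, Satb2 and Slc17a6), 5 of 22 GABAergic genes (Dlx1, Dlx6, Meis2, Slc32a1 and Sp9) and 4 of 12 forebrain patterning factors (Arx, Lhx2, Nr2f1 and Nr2f2). Radial glia and astrocyte (Nfia, Nfib and Sox2), pan-neuronal (Gap43 and Rbfox3), housekeeping (Ubc and Ywhaz), microglial (Ptprc) and cell cycle (Aurkb) genes were also among them. No member of any other list was, the oligodendrocyte precursor, immediate early, thalamic and hypothalamic, Hox, erythroid, lymphocyte, liver, muscle and myelin lists included. The members in this comparison were named after their values were seen. Their counts were neither tested nor set against the share over all genes.

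Distal peaks were enriched for motifs of several transcription factor families over GC-matched windows nearby. Of 19 motifs, 12 were more frequent and 4 less frequent in the peak windows. The MEF2 motif, bound by myocyte enhancer factors active in neurons, was in 1.74% of 32819 peak windows and 0.652% of background windows (odds ratio 2.70, 95% interval 2.31 to 3.16, adjusted p = 2.15e-38, Fisher's exact test). The odds ratio was 2.34 for EGR (1.33 to 3.97), 1.82 for RFX (1.66 to 1.99), 1.62 for POU (1.48 to 1.78), 1.45 for SP/KLF (1.31 to 1.61), 1.41 for homeobox (1.35 to 1.49), 1.38 for NFI (1.34 to 1.43), 1.36 for SOX (1.31 to 1.42) and 1.33 for ETS (1.09 to 1.63). EGR matches were few, in 42 peak windows and 18 background windows. The size of the EGR excess depended on the setting, at 1.49 in replicate 2's own list, 3.89 at the stricter threshold and 5.51 without GC matching, and SP/KLF had 2.75 without GC matching. The MyoD/Ascl E-box (1.24), the proneural E-box (1.14) and TEAD (1.07) had smaller excesses. In windows with under 10% repeat sequence the TEAD (1.02, adjusted p = 0.535) and ETS (1.02, adjusted p = 1.00) excesses were lost by Fisher's exact test, and ETS also did not pass in replicate 1's own list (0.0751), at the stricter threshold (0.0668) or in 200 bp windows (0.988). The motifs of CTCF (0.600, 0.533 to 0.676), the nuclear receptors (0.708, 0.684 to 0.733), T-box (0.742, 0.669 to 0.823) and AP-1 (0.925, 0.875 to 0.977) were rarer in peaks. CRE, GATA and HNF1 did not pass. In 1000 bp windows and without GC matching, however, CRE was more frequent in peaks (adjusted p = 0.00161 and 0.00823) and GATA rarer (9.58e-06 and 3.15e-05), and GATA was also rarer in windows with under 10% repeat sequence (0.0107, all Fisher's exact test). The homeobox direction turned without GC matching (odds ratio 0.905), and the CTCF direction turned in windows with under 10% repeat sequence (1.22, 0.997 to 1.49). The size of the CTCF deficit also depended on the window, with odds ratios of 0.363 in 200 bp windows and 0.793 in 1000 bp windows.

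**Figure D4:**
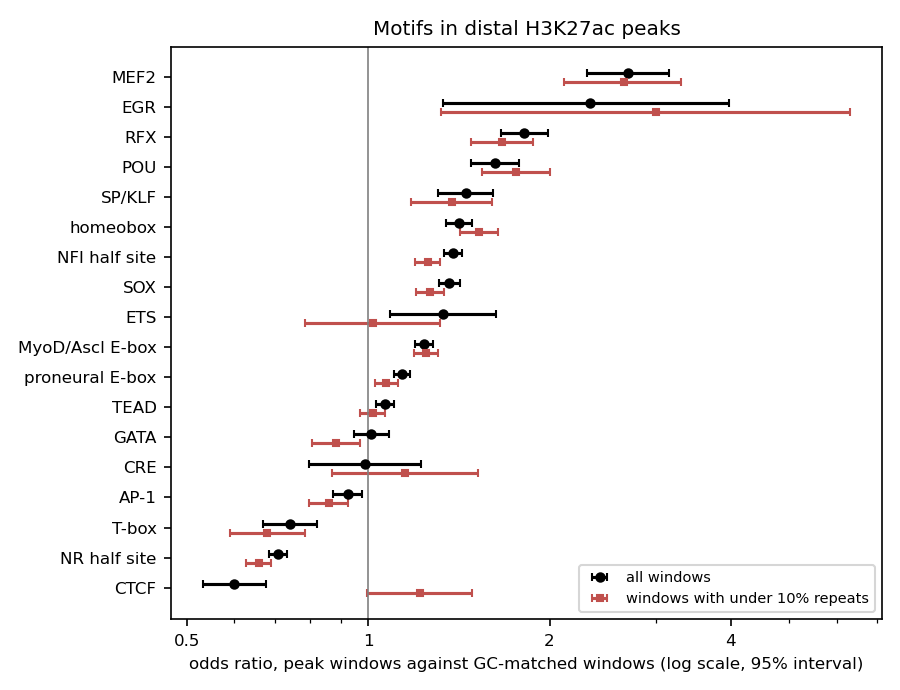
Odds ratio of each motif in windows on distal peaks against GC-matched windows (x axis, log scale, with 95% intervals), for all windows (black) and for windows with under 10% repeat sequence (red). MEF2 is highest over all windows (2.70), and CTCF moves from 0.600 to 1.22. In windows with few repeats EGR has the highest value (3.003, 1.32 to 6.30), from only 24 peak and 8 background windows with a match. Its interval holds the MEF2 value there (2.65). HNF1, with few matches, is not drawn.

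The X chromosome carried few peaks. It had 831 replicated peaks (4.86 per Mb), while autosomes had 18.9 per Mb and ranged from 14.5 on chromosome 14 to 27.9 on chromosome 11. Both replicates showed this, with 6.71 and 7.06 peaks per Mb of X. Of the X genes 37.8% had a promoter peak, against 54.1% of autosomal genes, and distal peaks came to 2.20 per Mb on X against 13.3. The Y chromosome held 4 replicated peaks. Both pools were of mixed sex, so the number of X and Y copies differed between cells.

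**Figure D5:**
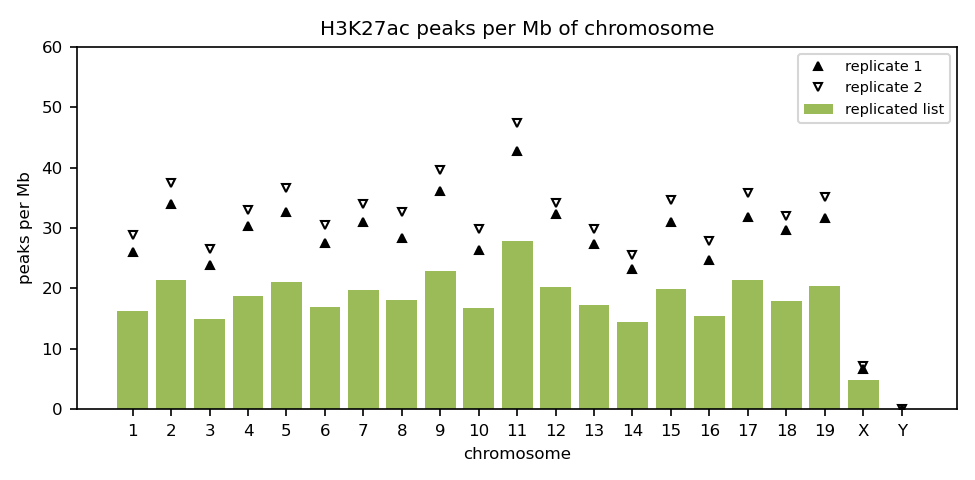
H3K27ac peaks per Mb (y axis) on each chromosome (x axis) for the replicated list (bars) and the replicates' own lists (triangles). X has 4.86 replicated peaks per Mb, below the lowest autosome (14.5).

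The last comparison asked whether the pools differed in cell types or dissection. For the 11391 genes with a promoter peak in both lists, the log2 ratio of replicate 1 to replicate 2 had an SD of 0.34, and 85 genes (0.746%) differed 2-fold or more. No gene list lay outside its random 95% range. Housekeeping genes were nearest, with a median of −0.14 at percentile 3.36. Lists with fewer than 3 such members, the erythroid, microglial and Hox lists among them, gave no value. The largest ratios were toward replicate 1 at Spaca6 (33.1 against 3.98), Slc26a8 (23.8 against 4.64), Ssc5d (17.7 against 3.58), Tbp (19.0 against 7.86) and Hist1h3a (16.0 against 7.59). Toward replicate 2 they were at Rhof (7.54 against 43.3), Gm26602 (6.39 against 26.7), Clec11a (5.32 against 19.9), Zfp36l1 (6.03 against 15.1) and Ptar1 (6.46 against 16.2). When each replicate's value was instead taken from peaks overlapping the same replicated promoter peak, only Ptar1 of these 10 still differed 2-fold (log2 ratio −1.26), and Spaca6 had 33.1 against 33.5. Promoter peaks of Slc26a8, Ssc5d, Tbp, Rhof and Gm26602 also lay within 1 kb of TSSs of Mapk14, Nat14, Psmb1, Setd1b and Med16 in turn, and those of Hist1h3a within 1 kb of TSSs of Hist1h4a and Hist1h1a, so these values do not belong to the named gene alone. With that matching the radial glia and astrocyte list fell outside its range, with a median of −0.28. With signal times width summed, which also carries peak width, 973 genes (8.54%) differed 2-fold or more and the GABAergic (0.35) and immediate early lists (0.48) fell outside their ranges.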

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

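In sequence outside the chromosomes, which no comparison used, 7 replicated peaks were listed on 5 unplaced or unlocalised sequences, more than the limit of 3 that a count of 0 allows. Their signal values ran from 3.09 to 39.1, with a median width of 734 bp. The replicates' own lists held 11 peaks each on such sequences and the pooled list 13. No explanation was tested, and with 1 group of 2 samples neither outlying samples nor differences between groups can be assessed.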

How the results depend on the processing

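The alternatives named as added in the processing section were chosen after the data were seen. No paired analysis was possible because there is only 1 group. At −log10 q of at least 5, replicate 1 kept 24089 peaks, replicate 2 22680 and the pooled list 34300, and the overlap was 78.3% of replicate 1 and 80.8% of replicate 2. The overlap was 38.7% and 35.02% with a reciprocal 50% rule, and 81.2% and 79.5% among the highest 20000 peaks. The Spearman correlation was 0.847 with the reciprocal rule, 0.777 on −log10 p and 0.859 at the stricter threshold. The share of replicated peaks held by both replicates was 84.2% at 1 bp and 10.6% at 90% coverage. The promoter share was 28.0% at 500 bp, 33.4% at 2.5 kb, 38.2% at the stricter threshold, 18.5% in the pooled list, and 21.9% to 23.6% in the replicates' own lists. The intergenic share was 22.6% at 2.5 kb, 21.4% at the stricter threshold, 25.8% in the pooled list, and 24.3% to 25.2% in the replicates' own lists. The number of gene lists with more promoter peaks stayed between 4 and 6 under all 8 alternatives, against 5. The number with fewer was 5 with CpG matching, against 10, and between 7 and 10 otherwise. The CpG-matched test could not call the microglial, erythroid, lymphocyte and liver lists lower. Lists with fewer distal peaks went from 2 to 1 with windows of 20 kb and 200 kb and at the stricter threshold (midbrain and hindbrain lost), and with 1 member per 100 kb (Hox lost, in a test that could not call it lower). Of the 15 highest clusters, 9 were overlapped by the 15 highest ranked by covered length and 9 by those distal from any annotated TSS, and 12 or 13 otherwise. Over 133 alternatives of single motifs, 117 kept their side of the threshold without a called change of direction, although CRE, GATA and HNF1, not called in the main comparison, often changed direction among these. The lost calls were CTCF (few repeats, adjusted p = 0.0752), ETS (few repeats, 1.00; 200 bp windows, 0.988; stricter threshold, 0.0668; without replicate 2, 0.0751), TEAD (few repeats, 0.535), EGR (0.155) and SP/KLF (0.0560) in 200 bp windows, and AP-1 in 200 bp windows (0.0716) and without GC matching (0.0552), all by Fisher's exact test. Several kept their size, with odds ratios of 0.919 for AP-1 and 2.001 for EGR in 200 bp windows and 1.29 for ETS at the stricter threshold. Without GC matching the log2 odds ratio was −0.14 for homeobox, −0.20 for GATA and 0.46 for CRE. In 1000 bp windows it was 0.38 for CRE and −0.16 for GATA. In windows with few repeats it was 0.29 for CTCF and −0.18 for GATA, and in 200 bp windows −0.038 for ETS. The number of lists outside their replicate range was 2 with signal times width summed (GABAergic and immediate early), 1 at 2.5 kb and 1 by matched peaks (both radial glia and astrocyte), and 973 genes differed 2-fold or more with signal times width, which also carries peak width. The X to autosome ratio of peaks per Mb was 0.307 at the stricter threshold, against 0.257 for all peaks, and 0.267 in the strongest quintile of distal peaks, against 0.165 for all distal peaks. Other than where the setting itself shows it, the cause was not tested. Unknown depth limits all statements on missing peaks.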

Other observations

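All tests below were chosen after the patterns were seen, and the tests on gene number and promoter signal of X and on microRNA genes by chance only after values that bear on them were seen. The 7 highest distal clusters each held annotated microRNA genes, and the other 8 of the first 15 held none. The same 7 each also held annotated long non-coding RNA genes, as did the clusters nearest to Chd2, Tuba1a and Sdccag8 among the other 8. A pattern of microRNA genes therefore cannot be told apart here from one of long non-coding RNA genes. The cluster at chromosome 7, 79496144 to 79550190, held Mir9-3 and its host gene, that on chromosome 13 held Mir9-2 and that on chromosome 3 held Mir9-1, so all 3 copies of the microRNA miR-9, a regulator of neural progenitors and neurons, lay in the 3 highest clusters. The fourth held Mir3089. The fifth, nearest to Wnt7b, held Mirlet7b and Mirlet7c-2. The sixth, on chromosome 14 from 64573731 to 64598092, held Mir124a-1, a copy of the neuronal microRNA miR-124, and the seventh, on chromosome 9, held Mir125b-1.

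Of the 472 clusters past the slope point, 37 (7.84%) held a microRNA gene, against a mean of 9.07 and a highest of 20 over 1000 shifts (two-sided permutation p = 0.00200, the smallest they can give), which argues against long clusters holding such genes by chance alone. Shifts do not keep gene density, and the 37 include the 7 clusters that raised the question. Of the next 472 clusters 10 held a microRNA gene, but these were not matched on length, so that count does not bear on it. The clusters were defined against coding TSSs, so a promoter of a non-coding gene counted as distal there. With peaks at any annotated TSS removed, 9 of the 15 highest clusters overlapped a new one among the 15 highest, which leaves open how far promoters of non-coding genes may account for the pattern. All 7 stayed past the slope point, but only those nearest to Cstad, Wnt7b and Ubash3b stayed among the 15 highest, while the 3 miR-9 clusters and the miR-124 cluster left them, and the removal takes whole wide peaks, those on the microRNA genes included. No biological explanation was tested.

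The X chromosome had 0.165 times the distal peaks per Mb of autosomes (95% interval 0.149 to 0.183). Lower depth on X as the whole cause was taken to predict a ratio of at least 0.66 in the strongest quintile, the ratio of coding genes per Mb being 0.659. The ratio there was 0.267 (0.223 to 0.319), below that bound, and in the weakest quintile it was 0.0827. However, the quintiles were cut on the signal value over all distal peaks, which lower depth on X may itself lower. X peaks could then leave the strongest quintile, so this test cannot decide on lower depth. Fewer genes on X as the whole cause is argued against by 0.701 distal peaks within 50 kb of X genes with a promoter peak, against 2.29 for autosomal ones (ratio 0.307, bootstrap 95% interval 0.243 to 0.377). A silent X in female nuclei remains open. The median promoter signal was 9.05 on X and 10.5 on autosomes (ratio 0.864, 0.790 to 0.910), an interval that crosses the bound of 0.85. Only genes with a promoter peak in the replicated list and both own lists entered (347 on X). Weakened X promoters could thus drop out and raise the ratio, and promoters were measured in place of distal peaks, so this test cannot decide. Mappability of X was not tested.

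Soft-masked repeats made up 12.3% of peak windows and 27.7% of background candidates, so repeats that carry a motif might make it look rarer in peaks. In windows with under 10% repeats the CTCF odds ratio went from 0.600 to 1.22 (0.997 to 1.49), as repeats in the background predict, and its deficit in the main comparison is a candidate effect of repeats. The nuclear receptor motif stayed rarer, at 0.659 (0.628 to 0.691), and so did T-box, at 0.680 (0.589 to 0.786), which argues against repeats as their cause. Why these motifs were rarer was not tested further, and no biological explanation was tested.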
